A study of Solanum lycopersicum with 12 samples.

How the data were processed

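Total RNA from whole breaker-stage MicroTom tomato fruits was labelled with biotin and hybridized to an Affymetrix tomato array, with 3 arrays for each of 4 genotypes (wild type, homozygous ORR, heterozygous ORR and an excision line). Per the labels, the authors used RMA from the affy package, which corrects background, normalizes arrays by quantiles and summarizes probe sets, and the deposited values are log2 expression values. The versions of affy and RMA are not given in the sources used here, nor is it stated whether the 12 arrays were normalized together. From the values themselves, each array ran between 2.77 and 14.4 with medians of 8.28 to 8.39. Whether the 3 arrays of a genotype came from separate plants is not stated, so their spread may be technical. Probe sets with endings such as _s_at and _x_at can bind transcripts of related genes.

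The table held 10209 probe sets. The 108 control probe sets were set aside and 10101 were tested. Gene names came from the probe annotation given with the data: 909 probe sets had 1 gene symbol, 0 had several and 9192 had none. In this way 802 genes could be named, and the named genes are a small part of what changed. No probe set was named for the NDH subunit M gene, for ACO1 or for E4, and these are not analysed here. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it in the gene lists.

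Groups were compared with limma 3.58.1 in R 4.3.3: a linear model of the log2 values on genotype over all 12 arrays, with moderated statistics and Benjamini-Hochberg adjustment over all 10101 probe sets within each comparison, 2-sided. A probe set was called at an adjusted p under 0.05. The fit had 8 residual degrees of freedom, a prior of 2.87 degrees of freedom and a prior SD of 0.139, and the median SE of a difference was 0.121 on the log2 scale. The comparisons were homozygous, heterozygous and excision against wild type, homozygous against excision, homozygous against heterozygous, and heterozygous against the midpoint of wild type and homozygous. Directions were also compared between homozygous minus wild type and heterozygous minus excision, and between heterozygous minus wild type and homozygous minus excision, with 100 simulated data sets of unchanged groups for chance. The model was tested on simulated data of 12 arrays with 200 of 10101 probe sets changed. There 85% of those changed by 1 log2 unit and 98% of those changed by 2 were called. In all 11 of 194 calls were of unchanged probe sets, and 0 were called in a comparison without change. The simulated noise was normal, independent between probe sets and arrays, and equal in spread across groups. The real arrays need not meet these settings, so the shares may differ there.

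The comparisons, 28 gene lists, the rule for naming genes and the alternatives below were fixed before the data were examined. Lists were matched to gene symbols and their synonyms; 23 had measured members, and the 20 with at least 3 genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The lists covered the carotenoid pathway, plastid isoprenoids, chlorophyll, photosynthetic light reactions, the Calvin cycle, the NDH complex, ethylene, ripening regulators, ripening-induced genes, and the cell wall. They also covered sugar and starch, respiration, glutamate and related amino acids, phenylpropanoids, sterols and alkaloids, tocopherols, antioxidant enzymes, heat shock proteins, pathogenesis-related proteins, jasmonate, abscisic acid, auxin, cytosolic and plastid ribosomal proteins, histones and the cell cycle, and markers of seed, epidermis and vascular tissue. Before any change was computed 21 members were dropped because their symbol matched a list by accident, such as an enolase in the cell wall list. Some matches by synonym stayed: the same enolase gene, PGH1, in the ethylene list (synonym ER28), and GABA-TP2 and gad2 in the sterol and alkaloid list (synonyms GAME12 and GAME11), which are also counted in the glutamate and GABA list. In all 19 genes belong to 2 lists, among them LE16 in the abscisic acid and epidermis lists. Camera passed 4, 2, 3, 6 and 2 of the 20 lists in the 5 comparisons of genotypes, in the order homozygous, heterozygous and excision against wild type, homozygous against excision and homozygous against heterozygous, and 0 with an estimated correlation. A list's median, mean and test differed in sign for 3, 3, 2, 5 and 4 lists in the same order, none of which passed.

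Genes are named in the text by this rule: RIN, NOR, Psy1, ACS2, ACS4, E8 and PG2 always; per comparison up to 10 raised and 10 lowered genes with the largest called change, arrays that do not overlap and an informative symbol (placeholder symbols without a synonym are left out); and up to 3 called members of each list, or 4 members of a list that passed. SUT4, a member of a list with 2 measured genes, and P69B in the comparison of homozygous with heterozygous fruits were named outside the rule after their values were seen. The alternatives tried were a block for the replicate number, a block for the code series of the arrays (AH85 to AH92 against AH105 to AH108), the AH85 to AH92 arrays alone, a second quantile normalization, median centring, leaving out probe sets below the 30th percentile of mean signal, fitting only the groups compared. Further alternatives were a trended robust prior, array weights, a 2-fold minimum, averaging the probe sets of a gene, and leaving out each array in turn. A different offset before the log was not applicable, since the values were already log2. The AH105 to AH108 series holds 1 array per genotype and gives no test of its own.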

Results

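Transcript levels were measured on an Affymetrix tomato array in whole MicroTom fruits picked at the breaker stage, the point at which green fruits begin to colour. The 12 arrays fell into 4 groups of 3: wild type, fruits homozygous for the ORR mutation, fruits heterozygous for it, and an excision line. ORR carries a transposable element in the gene for subunit M of the plastid NADH dehydrogenase-like (NDH) complex, and the fourth line is called an ORR excision line in the labels. Its sample titles read ex-35S-451. They do not state what this name stands for or whether the line carries a further construct. Array medians lay between 8.28 and 8.39 on the log2 scale, and the number of arrays limits the precision of each mean. Hybridization control spikes other than bioC averaged 10.37 ± 0.12 (SD, n = 3) in wild type, 9.90 ± 0.13 in homozygous, 9.96 ± 0.03 in heterozygous and 10.22 ± 0.08 in excision fruits. The spike bioC was set apart after its values were seen, because it differed by the code series of the arrays: its mean was 7.89 in the 4 AH105 to AH108 arrays and 9.06 in the 8 AH85 to AH92 arrays, a difference of -1.17. The median change of all probe sets stayed between -0.01 and 0.05 in every comparison.

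The reporter-class probe sets of the array were singled out after their values were seen, and the annotation does not identify which sequences they read. Of 63 such probe sets, 3 changed by at least 2-fold against wild type, and on these 3 every array of the ORR and excision lines lay above every wild-type array. RPTR-Les-A06498-1_at read 4.94 ± 0.22 (log2, SD, n = 3) in wild type, 11.43 ± 0.02 in homozygous, 12.27 ± 0.15 in heterozygous and 8.84 ± 1.13 in excision fruits. RPTR-Les-X17220-1_at read 3.85 ± 0.12, 7.06 ± 0.28, 7.70 ± 1.51 and 8.91 ± 0.25 in the same order. The first was lower in the excision line than in homozygous fruits by a log2 change of 2.59 (SE 0.41, adjusted p = 0.000783), and the second was higher there (homozygous minus excision -1.85, SE 0.55, adjusted p = 0.0231).

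**Figure D1:**
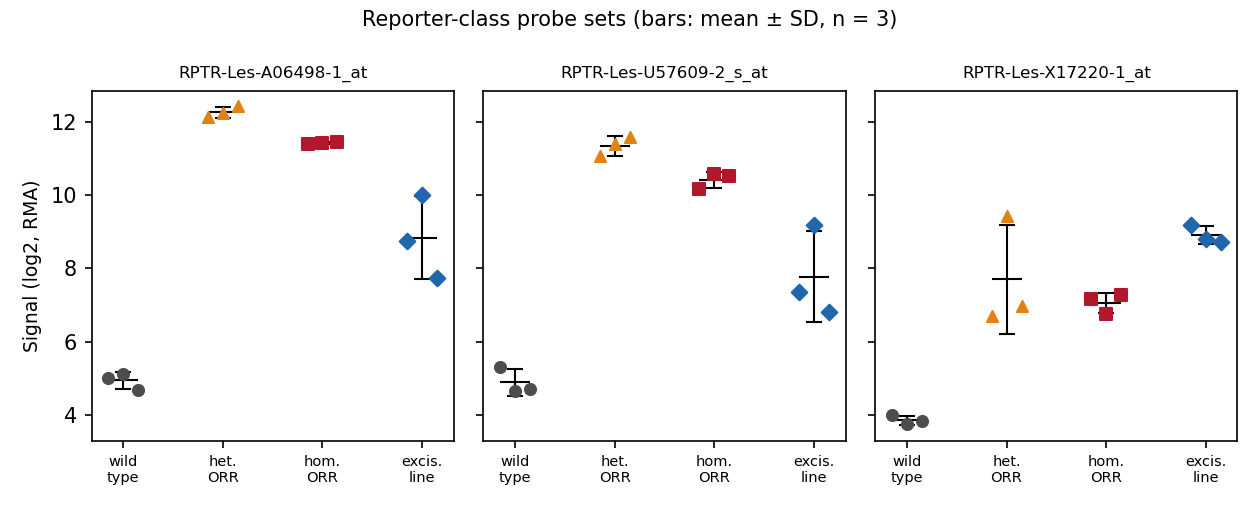
Log2 signal (vertical axis) of the 3 reporter-class probe sets that changed by at least 2-fold against wild type, per array, with means and SD (n = 3 per genotype). Every array of the heterozygous, homozygous and excision lines lies above the 3 wild-type arrays.

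Across all probe sets the homozygous and heterozygous ORR arrays lay apart from the wild-type and excision arrays. The first principal component held 65.1% of the variance and placed the homozygous arrays between 23.1 and 32.9 and the heterozygous arrays between 32.4 and 37.2, with wild-type and excision arrays between -42.9 and -21.0. The second component held 13.8% and separated wild type (-23.0 to -18.1) from excision replicates 1 and 2 (18.6 and 32.0), with excision replicate 3 at -2.27. Correlations between heterozygous and homozygous arrays ran from 0.990 to 0.995 across probe sets, which are not independent replicates, against 0.956 to 0.976 between homozygous and wild-type arrays.

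**Figure D2:**
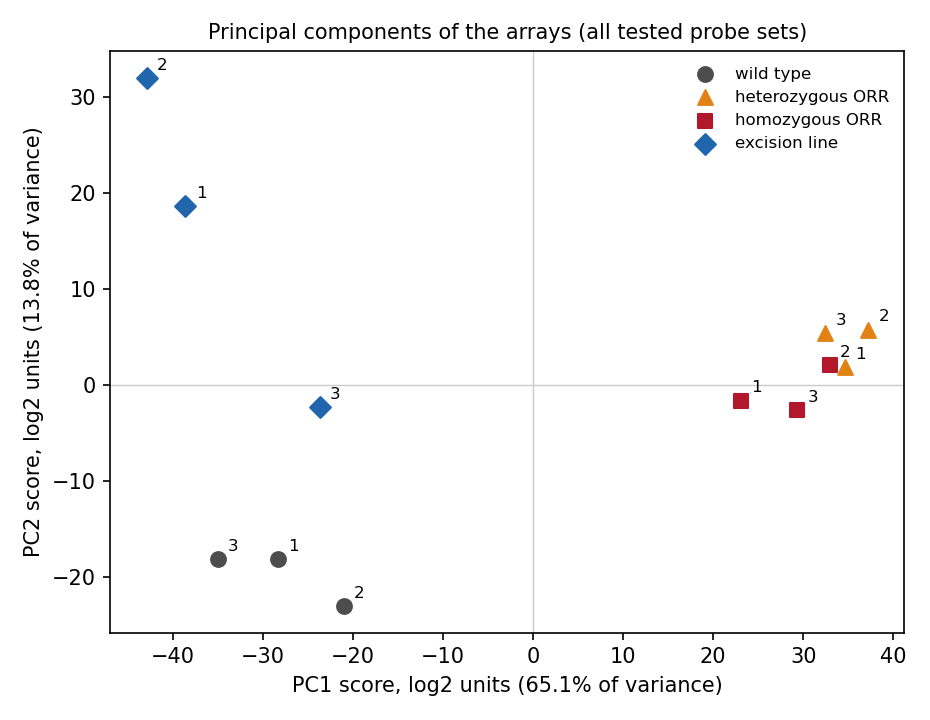
Scores of the 12 arrays on the first (horizontal) and second (vertical) principal components of the log2 values; digits are replicate numbers. ORR arrays lie at 23.1 or above on the first component and wild-type and excision arrays at -21.0 or below.

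Homozygous ORR fruits were compared with wild type to ask which transcripts differ in mutant fruits at the breaker stage. Transcripts of pathogenesis-related proteins were much higher in the mutant. The chitinase gene CHI3 rose from 9.72 ± 0.16 to 12.79 ± 0.11 (log2, SD, n = 3), a log2 change of 3.07 (SE 0.12, adjusted p = 1.56e-07), and the chitinase genes CHI17 and CHI14 rose by 1.90 (SE 0.11) and 2.59 (SE 0.15). The PR-1 genes P4 and PR1b1 rose by 2.95 (SE 0.18) and 2.75 (SE 0.24), the subtilisin-like protease gene P69B by 2.89 (SE 0.14) and the osmotin-like NP24-I by 2.72 (SE 0.38). Of 14 measured members of the list, 10 rose, 0 fell and 4 did not pass; adjusted over the list alone, 10 rose and 1 fell. The list's median log2 change was 2.09 (camera adjusted p = 1.45e-06), with adjusted p = 0.139 with an estimated correlation. A second probe set for PR1b1 changed by -0.22 and was not called.

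Genes of photosynthesis were also higher in homozygous fruits. The chlorophyll a/b-binding protein gene CAB5 rose by 2.02 (SE 0.22, adjusted p = 6.58e-05), photosystem I subunit D (LOC543978) by 1.19 (SE 0.15), and the oxygen-evolving complex genes PSBO and PsbQ by 0.76 (SE 0.10) and 0.73 (SE 0.07). All 9 measured members of the light-reaction list rose, also when adjusted over the list alone, with a median of 0.76 (camera adjusted p = 2.99e-05; adjusted p = 0.190 with an estimated correlation). Both measured chlorophyll genes rose: GSA-AT by 0.39 (SE 0.10) and POR2 by 0.59 (SE 0.14), with both calls lost on the 2 arrays per group of the AH85 to AH92 code series. AOX1a, the mitochondrial alternative oxidase, rose by 1.43 (SE 0.14, adjusted p = 3.31e-05), and PTOX, the plastid terminal oxidase, by 0.49 (SE 0.08). With malate dehydrogenase (mdh), they are the 3 measured members of the respiration list; 3 rose, and 3 rose adjusted over the list alone (median 0.49, camera adjusted p = 0.0312; adjusted p = 0.190 with an estimated correlation). That list's call was lost with the replicate number as a block (adjusted p = 0.0515), in the AH85 to AH92 series (adjusted p = 0.0759), without dim probe sets (adjusted p = 0.0696) and when only the compared groups were fitted (adjusted p = 0.0522). Its median stayed at 0.49 in these settings except the AH85 to AH92 series, where it was 0.54.

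The ripening regulators moved in both directions. RIN, a MADS-box factor required for ripening (Entrez Gene 543708), rose from 7.25 ± 0.23 to 9.87 ± 0.40, a log2 change of 2.62 (SE 0.30, adjusted p = 9.92e-05). NOR, a NAC factor required for ripening (Entrez Gene 778200), rose from 6.60 ± 0.85 to 10.29 ± 1.02, a change of 3.69 (SE 0.54, adjusted p = 0.000485), while the MADS-box gene TDR4 fell by 0.59 (SE 0.10). Of the 9 regulators, 3 rose, 3 fell and 3 did not pass; adjusted over the list alone, 3 rose and 4 fell (camera adjusted p = 0.984). Of 18 ripening-induced genes, 4 rose and 3 fell, and the same numbers held adjusted over the list alone (camera adjusted p = 0.887); RIN and NOR belong to both lists. E8, an ethylene-regulated ripening gene, changed by -0.08 (SE 0.49, adjusted p = 0.920), the ripening polygalacturonase PG2 by -0.29 (SE 1.04, adjusted p = 0.856) and ACS2, an ACC synthase of ripening, by 0.42 (SE 0.25, adjusted p = 0.214); none of the 3 passed. Psy1, the phytoene synthase of fruit, changed by 0.41 (SE 0.14, adjusted p = 0.0449) on its brightest probe set. The value ranged from -0.56 to 0.41 over its 3 probe sets. The call was lost when any array other than homozygous replicate 1 or excision replicate 3 was left out, with adjusted p from 0.0510 (without excision replicate 1) to 0.165 (without homozygous replicate 3).

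Among the 10 largest decreases of named genes were ACS3 and ACS1A of ethylene synthesis and AOS of jasmonate synthesis. Neither the ethylene list nor the jasmonate list passed its test. The ACC synthase genes ACS3 and ACS1A fell by 3.21 (SE 0.40) and 2.23 (SE 0.29), and the response factor gene ERF3 fell by 1.66 (SE 0.13, adjusted p = 9.45e-06) on its brighter probe set, while its other one changed by -0.04 and was not called. ACS4 changed by -0.39 (SE 0.12, adjusted p = 0.0247), a call lost without wild-type replicate 1 (0.0698), wild-type replicate 3 (0.0772) or homozygous replicate 2 (0.101). In the ethylene list 7 of 43 genes rose and 13 fell, 8 and 14 adjusted over the list alone (camera adjusted p = 0.355). LOX1.1, a lipoxygenase, fell from 13.43 ± 0.06 to 11.39 ± 0.35 (change -2.03, SE 0.15, adjusted p = 5.76e-06), and AOS, the allene oxide synthase of jasmonate synthesis, fell by 2.56 (SE 0.49). In the jasmonate list, which also covers lipoxygenases such as LOX1.1, 3 of 17 rose and 4 fell, 3 and 5 adjusted over the list alone (camera adjusted p = 0.407).

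Cell wall genes fell more often than they rose. The xyloglucan-modifying genes XTH3 and XTH9 (LOC543916) fell by 3.62 (SE 0.36) and 3.39 (SE 0.36), and the expansin gene EXPA6 by 1.45 (SE 0.16), whereas XTH16 rose by 1.72 (SE 0.14, adjusted p = 1.10e-05). Of 43 members 5 rose and 16 fell, the same numbers adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.0312; adjusted p = 0.485 with an estimated correlation). The list's call was lost with median-centred arrays (median -0.27, adjusted p = 0.0509) and without dim probe sets (median -0.24, adjusted p = 0.0595). The related gene tXET-B2, which is not in the list, fell by 3.92 (SE 0.60). The epidermal lipid-transfer protein genes LE16 and ltpg1 fell by 1.65 (SE 0.18) and 0.96 (SE 0.08). Of the 2 measured vascular genes SUT2 changed by -0.54 (SE 0.16, adjusted p = 0.0215) and SUT4 did not pass. The SUT2 call was lost without homozygous replicate 2 (-0.45, adjusted p = 0.0882) or wild-type replicate 3 (-0.39, adjusted p = 0.0763).

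Single steps of the plastid isoprenoid and carotenoid pathways changed, and neither list passed its test. DXS, the entry enzyme of plastid isoprenoid synthesis, rose from 9.18 ± 0.03 to 10.19 ± 0.09 (SE of the change 0.09, adjusted p = 1.96e-05) and the lycopene epsilon-cyclase gene CRTL-E-1 rose by 0.71 (SE 0.12). NCED1, which opens abscisic acid synthesis, fell by 1.07 (SE 0.11). Of 13 carotenoid genes 3 rose and 5 fell, and of 4 isoprenoid genes 2 rose and 0 fell, each with the same numbers adjusted over the list alone (camera adjusted p = 0.355 for both). The dehydrin gene TAS14 fell by 1.85 (SE 0.21); of 4 abscisic acid genes, among them LE16, also counted above as epidermal, 0 rose and 2 fell, 1 and 3 adjusted over the list alone (camera adjusted p = 0.150). Of 7 auxin-response genes 0 rose and 4 fell, IAA17 by 1.61 (SE 0.34; -0.46 and not called on its other probe set), with 1 and 4 adjusted over the list alone (camera adjusted p = 0.186).

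The other lists held single changes. The lignin gene CCR1 rose by 1.44 (SE 0.11) and the chalcone synthase genes CHS1 and CHS2 each fell by 1.26 (SE 0.20 and 0.18); 1 of 6 phenylpropanoid genes rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.556). The starch gene AGPL3 rose by 1.09 (SE 0.14); 4 of 21 sugar and starch genes rose and 5 fell, 5 and 5 adjusted over the list alone (camera adjusted p = 0.887). The catalase gene cat1 rose by 0.81 (SE 0.08); 3 of 13 antioxidant genes rose and 1 fell, 3 and 0 adjusted over the list alone (camera adjusted p = 0.498). The cyclin-dependent kinase gene CDKA1 fell by 1.05 (SE 0.13) and the histone gene H1 rose by 0.49 (SE 0.07; 0.03 and not called on its other probe set), 2 of 13 cell-cycle and histone genes rising and 2 falling (camera adjusted p = 0.469). Among 8 glutamate, GABA and branched-chain amino acid genes 2 rose and 3 fell (camera adjusted p = 0.445). Among 3 sterol and alkaloid genes, 2 of which (GABA-TP2 and gad2) also count in the list before, 0 rose and 1 fell (camera adjusted p = 0.355), and among 4 heat shock genes 0 rose and 1 fell (camera adjusted p = 0.445). Among 5 cytosolic ribosomal genes limma called 0 (camera adjusted p = 0.887). These 5 lists gave the same numbers adjusted over the list alone. No probe set was named for the Calvin cycle, NDH complex, tocopherol, plastid ribosomal or seed lists.

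In all, 3516 of 10101 probe sets differed between homozygous and wild-type fruits, 1934 higher and 1582 lower, and 762 of them by at least 2-fold (289 higher, 473 lower). The balance of directions thus turned among the 2-fold calls, and also with median-centred arrays, which gave 1573 higher and 1910 lower. The 3 arrays of each group did not overlap for 3432 of the 3516 and for 48.1% of all probe sets, where chance gives 10%. In the AH85 to AH92 series alone, with 2 arrays per group, 2027 were called.

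**Figure D3:**
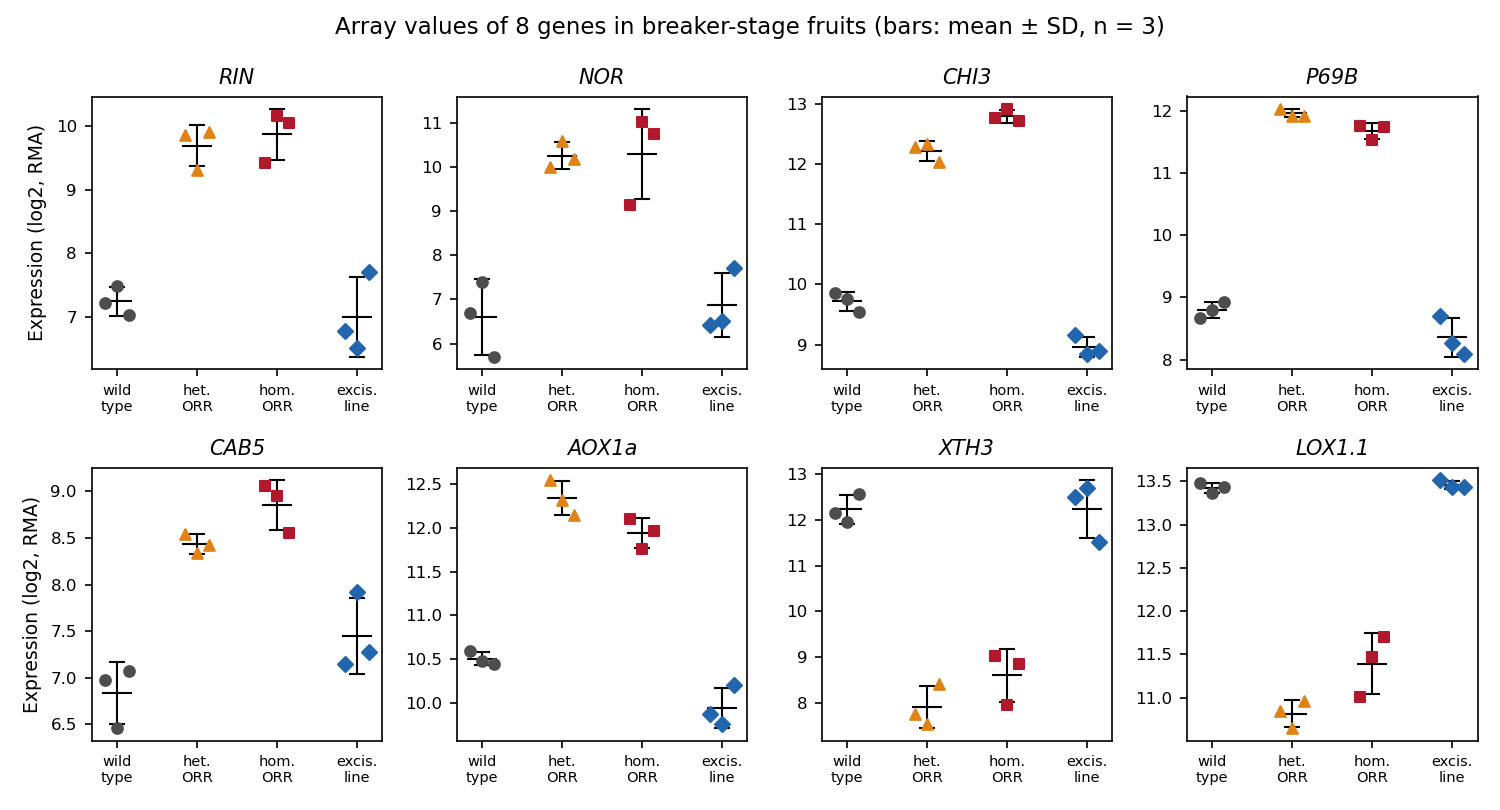
Log2 expression (vertical axes) of 8 genes per array in the 4 genotypes, with means and SD (n = 3). In both ORR genotypes RIN, NOR, CHI3, P69B, CAB5 and AOX1a lie above, and XTH3 and LOX1.1 below, all wild-type and excision arrays.

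Heterozygous fruits were compared with wild type to ask which transcripts differ with a single mutant copy. Pathogenesis-related genes were again higher: P4 rose by 3.47 (SE 0.18, adjusted p = 2.41e-07), P69B by 3.17 (SE 0.14), CHI14 by 2.90 (SE 0.15) and CHI3 by 2.50 (SE 0.12). Of the 14 members 12 rose and 0 fell, the same adjusted over the list alone, with a median of 2.22 (camera adjusted p = 1.23e-07; adjusted p = 0.0925 with an estimated correlation). RIN rose by 2.45 (SE 0.30, adjusted p = 0.000107) and NOR by 3.65 (SE 0.54). E8 (-0.35, SE 0.49, adjusted p = 0.603), PG2 (-1.16, SE 1.04, adjusted p = 0.403), ACS2 (-0.02, SE 0.25, adjusted p = 0.951) and Psy1 (0.15, SE 0.14, adjusted p = 0.422) did not pass. PG2 passed once wild-type replicate 3 was left out (-2.56, adjusted p = 0.0202). Light-reaction genes rose in 8 of 9 cases, 9 of 9 adjusted over the list alone, with CAB5 at 1.60 (SE 0.22). The list had a median of 0.71 (camera adjusted p = 0.000936; adjusted p = 0.477 with an estimated correlation).

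In heterozygous fruits XTH3 changed by -4.32 (SE 0.36) and TAS14 by -3.30 (SE 0.21, adjusted p = 1.06e-06). ACS3 changed by -3.10 (SE 0.40), LOX1.1 by -2.61 (SE 0.15) and NCED1 by -1.76 (SE 0.11). ACS4 fell by 0.43 (SE 0.12, adjusted p = 0.0139), a call lost in the AH85 to AH92 series (adjusted p = 0.0684). The cell-wall invertase gene Wiv-1 rose by 3.03 (SE 0.36) and AOX1a by 1.83 (SE 0.14). Of 43 cell wall genes 7 rose and 12 fell (camera adjusted p = 0.225) and of 43 ethylene genes 8 rose and 16 fell (camera adjusted p = 0.248), the same numbers adjusted over the list alone. Of 13 carotenoid genes 2 rose and 6 fell, 2 and 7 adjusted over the list alone (camera adjusted p = 0.102; the list passed without dim probe sets, adjusted p = 0.0236). The epidermal genes LE16 and ltpg1 fell by 2.01 (SE 0.18) and 1.28 (SE 0.08). In all, 4100 probe sets differed, 2308 higher and 1792 lower, 912 of them by at least 2-fold (384 higher, 528 lower). Median-centred arrays turned the balance as well, to 1781 higher and 2292 lower. Of the 4100, 4024 had arrays that did not overlap, against 52.3% of all probe sets and 10% by chance. In the AH85 to AH92 series 2442 were called.

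**Figure D4:**
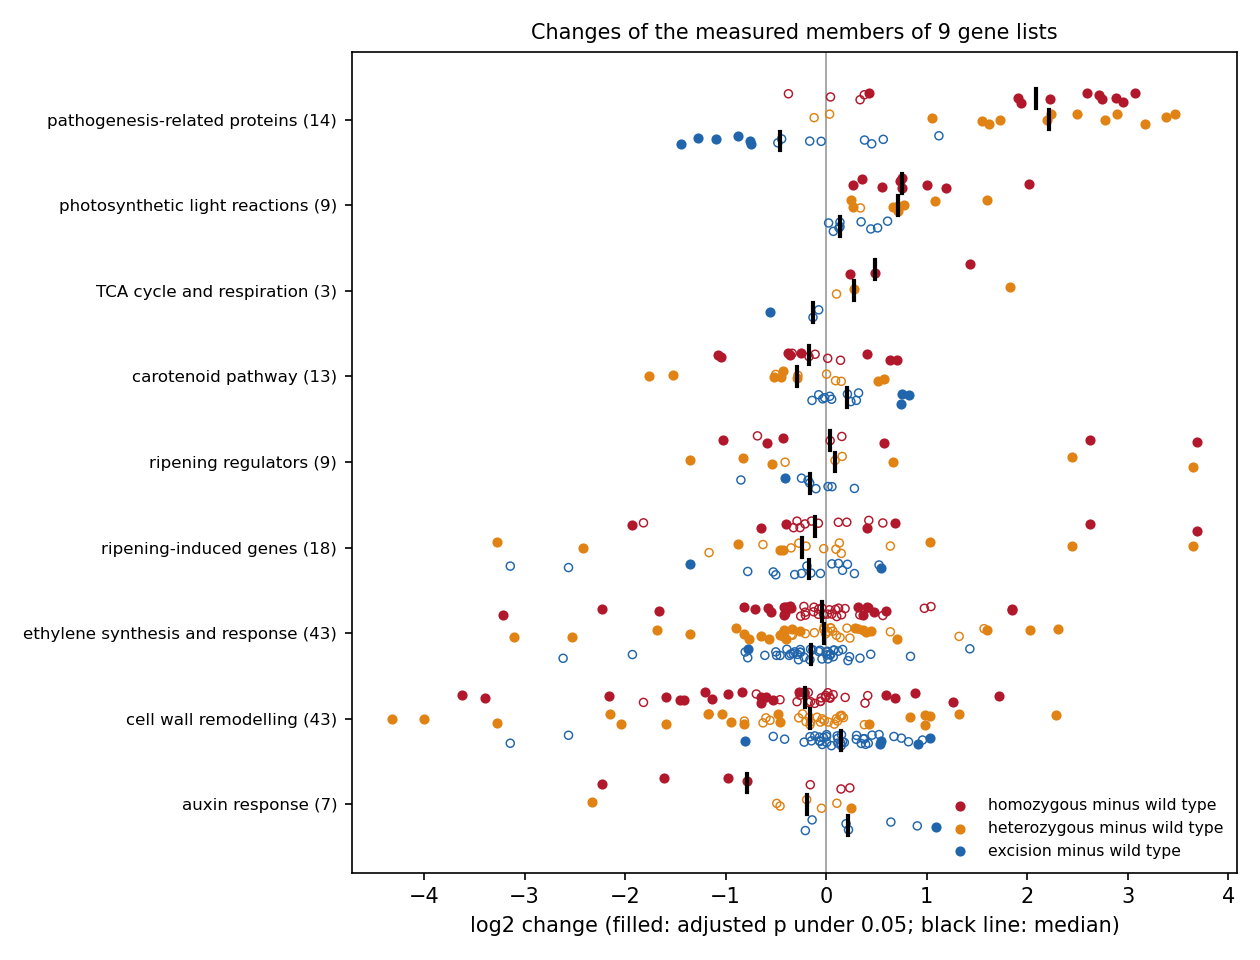
Log2 change against wild type (horizontal axis) of each measured member of 9 gene lists in homozygous, heterozygous and excision fruits; filled points passed an adjusted p of 0.05 and black lines are medians. The pathogenesis-related medians are 2.09, 2.22 and -0.46 in that order.

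The line called an excision line was compared with wild type. The 3 reporter probe sets above still read higher there than in wild type, so the arrays do not show what this line has lost. Here the chitinase genes CHI17 and CHI3 fell, by 1.45 (SE 0.11, adjusted p = 0.000300) and 0.75 (SE 0.12, adjusted p = 0.00997), and pip1 fell by 2.17 (SE 0.32, adjusted p = 0.00766). The endoglucanase gene cel7 rose by 1.04 (SE 0.14, adjusted p = 0.00485), the subtilase gene SBT2 by 1.11 (SE 0.17), the histone gene H1 by 0.59 (SE 0.07; 0.42 and not called on its other probe set) and the expansin gene EXPA3 by 0.54 (SE 0.07). These 7 genes kept the call whichever array was left out, but lost it in the AH85 to AH92 series, and all of them except CHI17 also lost it when only the compared groups were fitted. RIN (-0.24, SE 0.30, adjusted p = 0.661), NOR (0.28, SE 0.54, adjusted p = 0.790), E8 (-0.78, SE 0.49, adjusted p = 0.337), Psy1 (0.21, SE 0.14, adjusted p = 0.371) and ACS4 (0.12, SE 0.12, adjusted p = 0.553) did not pass. PG2 (-2.56, SE 1.04, adjusted p = 0.150) and ACS2 (-0.50, SE 0.25, adjusted p = 0.233) did not pass either, but passed without wild-type replicate 3 (PG2 -3.96, adjusted p = 0.0266) and without excision replicate 3 (ACS2 -0.77, adjusted p = 0.0364).

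Of the 14 pathogenesis-related genes 0 rose and 6 fell in the excision line, 1 and 8 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.00643; adjusted p = 0.345 with an estimated correlation). The call was lost without excision replicate 3 (adjusted p = 0.139) and with array weights (adjusted p = 0.0590). Light-reaction genes had a median of 0.14 with 0 of 9 passing, 2 adjusted over the list alone (camera adjusted p = 0.0240), and the 4 abscisic acid genes a median of -0.51 with 1 lower, 3 adjusted over the list alone (camera adjusted p = 0.0242). Both had an adjusted p = 0.345 with an estimated correlation, and both calls were lost without wild-type replicate 2 (adjusted p = 0.116) or excision replicate 2 (adjusted p = 0.0554) and with array weights (adjusted p = 0.0590). Adjusted over the list alone, 5 of 43 cell wall genes rose and 1 fell, 3 of 13 carotenoid genes rose and 0 fell, and 1 of 17 jasmonate genes rose and 7 fell. Over all genes the numbers were 4 and 1, 3 and 0, and 0 and 3 (camera adjusted p = 0.0505, 0.0825 and 0.0589). The side of the threshold changed with the setting. The cell wall list passed in 13 settings (adjusted p from 0.0195 to 0.0467), among them leaving out wild-type replicate 1 (0.0467) or 3 (0.0358), homozygous replicate 1 (0.0420), heterozygous replicate 1 (0.0453), 2 (0.0407) or 3 (0.0409), or excision replicate 3 (0.0355). The jasmonate list passed in 4 (adjusted p from 0.0353 to 0.0483), among them without wild-type replicate 3 (0.0405), and the carotenoid list without wild-type replicate 3 (adjusted p = 0.0357). The ethylene list, with 0 of 43 genes higher and 1 lower (0 and 0 adjusted over the list alone), had a median of -0.15 (camera adjusted p = 0.0825) and passed without dim probe sets (adjusted p = 0.0340) or wild-type replicate 3 (adjusted p = 0.0380).

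In all, 722 probe sets differed between excision and wild-type fruits, 387 higher and 335 lower, 146 of them by at least 2-fold (70 higher, 76 lower). Which direction held the majority depended on the setting, with 342 higher and 393 lower with median-centred arrays, 892 and 979 with array weights, 150 and 153 without wild-type replicate 3, and 4 and 19 with only the compared groups fitted. All 722 had arrays that did not overlap, against 24.4% of all probe sets and 10% by chance. This count rested on single arrays: it was 1831 without excision replicate 3, 141 and 136 without excision replicates 1 and 2, 240, 340 and 303 without wild-type replicates 1, 2 and 3, between 440 and 452 without any 1 of heterozygous replicates 1, 2 and 3, and 423 and 396 without homozygous replicates 2 and 3. In the AH85 to AH92 series limma called 0, with 1792 at an unadjusted p under 0.05, and with only these 2 groups fitted it called 23. The count of 722 thus depends on a spread per probe set estimated over all genotypes, the ORR arrays included.

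Homozygous fruits were also compared with the excision line, which uses none of the wild-type arrays as the reference. CHI3 and CHI17 were higher in homozygous fruits by 3.83 (SE 0.12, adjusted p = 1.56e-08) and 3.35 (SE 0.11), PR1b1 by 3.84 (SE 0.24) and P4 by 3.83 (SE 0.18). The second PR1b1 probe set differed by 0.06 and was not called. Of the 14 pathogenesis-related genes 11 were higher and 0 lower, 11 and 1 adjusted over the list alone (median 2.62, camera adjusted p = 7.30e-07; adjusted p = 0.124 with an estimated correlation). RIN and NOR were higher by 2.87 (SE 0.30, adjusted p = 5.08e-05) and 3.41 (SE 0.54), and AG1, another MADS-box gene, by 0.76 (SE 0.13). E8 (0.70, SE 0.49, adjusted p = 0.291), PG2 (2.27, SE 1.04, adjusted p = 0.115) and Psy1 (0.19, SE 0.14, adjusted p = 0.319) did not pass. PG2 passed without wild-type replicate 3 (adjusted p = 0.0200) and Psy1 without homozygous replicate 1 (0.38, adjusted p = 0.0131). Over the 3 probe sets of Psy1 the value ranged from -1.03 to 0.19, and the one at -1.03 was called (adjusted p = 0.00539). ACS2 was higher by 0.92 (SE 0.25, adjusted p = 0.0150), a call lost without homozygous replicate 3 (0.74, adjusted p = 0.0645), and ACS4 was lower (-0.52, SE 0.12, adjusted p = 0.00628), a call lost in the AH85 to AH92 series (adjusted p = 0.0772).

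In the same comparison 7 of 9 light-reaction genes were higher, also adjusted over the list alone (median 0.62, camera adjusted p = 0.00289; adjusted p = 0.287 with an estimated correlation). The 3 members of the respiration list, among them the plastid oxidase gene PTOX, were higher too, with AOX1a at 1.99 (SE 0.14). That list's median was 0.62 (camera adjusted p = 0.00948, and 0.173 with an estimated correlation). Of 43 cell wall genes 3 were higher and 16 lower, also adjusted over the list alone (median -0.17, camera adjusted p = 0.00215; adjusted p = 0.287 with an estimated correlation), among them the expansin gene EXPA4 (-2.98, SE 0.26) and XTH3 (-3.62, SE 0.36). Both epidermal genes were lower too, LE16 by 1.34 (SE 0.18, adjusted p = 0.000225) and ltpg1 by 1.05 (SE 0.08). Of 13 carotenoid genes 1 was higher and 7 lower, 1 and 8 adjusted over the list alone (median -0.37, camera adjusted p = 0.00948; adjusted p = 0.298 with an estimated correlation), with the beta-carotene hydroxylase gene CrtR-b1 at -1.16 (SE 0.20). Of 7 auxin-response genes 0 were higher and 4 lower, also adjusted over the list alone, with IAA17 at -2.52 (SE 0.34) and IAA3 at -2.45 (SE 0.39). That list's median was -1.43 (camera adjusted p = 0.0422; adjusted p = 0.287 with an estimated correlation). Its call was lost in 8 settings, among them homozygous replicate 2 (adjusted p = 0.0550) or excision replicate 1 (adjusted p = 0.0712) left out and the AH85 to AH92 series (adjusted p = 0.0991). The heat shock list (median -0.49, camera adjusted p = 0.345) passed without excision replicate 1 (adjusted p = 0.0479).

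In all, 3516 probe sets differed between homozygous and excision fruits, 1929 higher and 1587 lower, 900 of them by at least 2-fold (346 higher, 554 lower). Here too the balance turned among the 2-fold calls and with median-centred arrays, to 1602 higher and 1760 lower. Of the 3516, 3410 had arrays that did not overlap, against 47.8% of all probe sets and 10% by chance. In the AH85 to AH92 series 1808 were called.

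The direction of the changes was also compared between sets of arrays with none in common. Of the 3516 probe sets called in homozygous minus wild type, 3290 (93.6%) had the same sign in heterozygous minus excision, 2454 were called there in the same direction and 27 in the opposite one. In 100 simulated data sets of unchanged groups the share with the same sign ran from 30.5% to 68.2%. RIN, NOR, CHI3, CAB5 and AOX1a were higher, and XTH3, ACS3 and LOX1.1 lower, in both ORR genotypes than in either reference. Of the 4100 probe sets called in heterozygous minus wild type, 3762 (91.8%) had the same sign in homozygous minus excision, where simulated sets gave 37.4% to 61.4%.

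**Figure D5:**
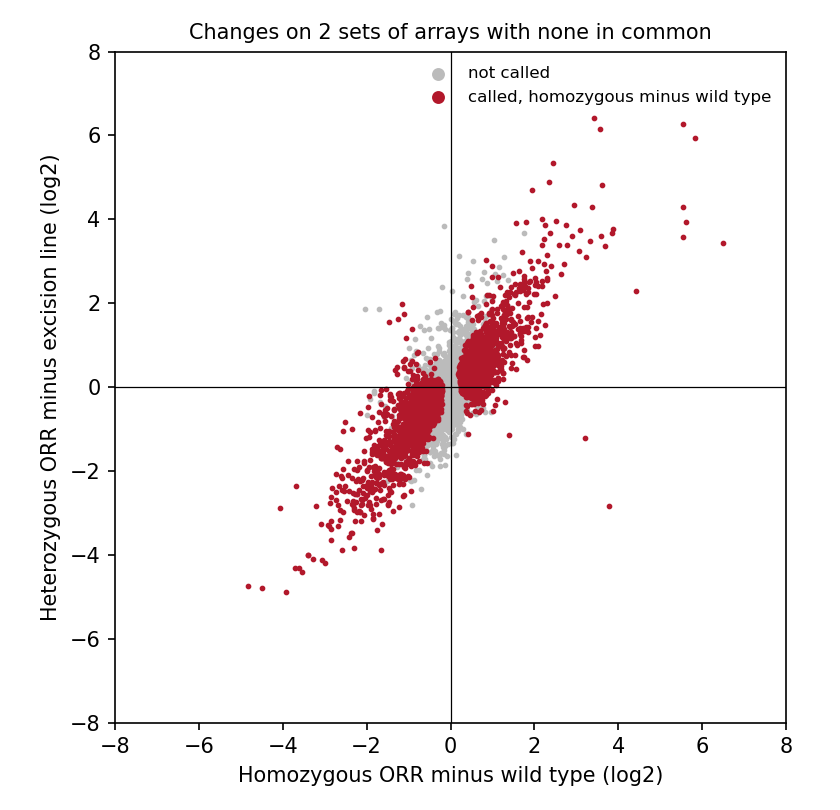
Log2 change of each probe set in homozygous minus wild type (horizontal axis) and in heterozygous minus excision (vertical axis); red points were called in the first. Of the 3516 red points 93.6% have the same sign on both axes.

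Homozygous and heterozygous fruits were compared to ask whether the number of mutant copies matters. RIN differed by 0.18 (SE 0.30, adjusted p = 1), NOR by 0.04 (SE 0.54, adjusted p = 1) and P69B by -0.28 (SE 0.14), and none of these passed. The pathogenesis-related gene PR-5 was lower in homozygous fruits (-1.30, SE 0.14, adjusted p = 0.00121), as was h52 (-1.76, SE 0.13, adjusted p = 0.000136), and both kept the call whichever array was left out. PR-5 lost it in the AH85 to AH92 series (adjusted p = 0.0887). TAS14 was higher by 1.44 (SE 0.21, adjusted p = 0.00917), a call lost without homozygous replicate 3 (1.31, adjusted p = 0.0581). E8 (0.27, SE 0.49), PG2 (0.87, SE 1.04), ACS4 (0.04, SE 0.12), ACS2 (0.45, SE 0.25) and Psy1 (0.25, SE 0.14) did not pass. The carotenoid list had a median of 0.17 with 1 of 13 genes higher, also adjusted over the list alone (camera adjusted p = 0.00250; adjusted p = 0.407 with an estimated correlation). The abscisic acid list had a median of 0.28 with 1 of 4 higher, also adjusted over the list alone (camera adjusted p = 0.0120; adjusted p = 0.407 with an estimated correlation), a call lost without homozygous replicate 2 (adjusted p = 0.0819). Other lists passed only in some settings. The pathogenesis-related list (median -0.29, camera adjusted p = 0.0711) passed in 8 (adjusted p from 0.0127 to 0.0450), among them homozygous replicate 3 (0.0385), heterozygous replicate 1 (0.0450) or excision replicate 1 (0.0328) or 3 (0.0205) left out. The ripening-induced list (median 0.15, camera adjusted p = 0.0997) passed in 4 (0.00160 to 0.0450), among them without homozygous replicate 1 (0.00436) or heterozygous replicate 1 (0.0450). Light-reaction genes (median 0.09, camera adjusted p = 0.0739) passed without homozygous replicate 3 (0.0102) and with only the compared groups fitted (0.0474). Cell wall genes (median -0.04, camera adjusted p = 0.128) passed in the AH85 to AH92 series (0.0288).

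In all, 85 probe sets differed between homozygous and heterozygous fruits, 33 higher and 52 lower, 30 of them by at least 2-fold; all 85 had arrays that did not overlap, against 17.5% of all probe sets and 10% by chance. The count was 52 without wild-type replicate 1, 33 and 27 without homozygous replicates 2 and 3, 38, 27 and 51 without heterozygous replicates 1, 2 and 3, and 12 in the AH85 to AH92 series. Array weights raised it to 408.

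Heterozygous levels were then set against the midpoint of wild type and homozygous. Of 10101 probe sets 2042 lay off that midpoint, 1143 above and 899 below, a balance that turned to 862 above and 1131 below with median-centred arrays and to 144 above and 171 below among 2-fold departures. Of the 2042, 1714 also differed between homozygous and wild-type fruits. Among the 1714 the heterozygote lay on the homozygous side for 1702 and on the wild-type side for 12. Of these 1702, 1492 lay beyond the homozygote mean, and a call for departure from the midpoint favours such probe sets. For probe sets chosen from the excision comparison, and so without the wild-type arrays as the reference, the 1929 that were higher had a median change against wild type of 0.44 in homozygous and 0.48 in heterozygous fruits, and the 1587 that were lower had medians of -0.57 and -0.59. The heterozygote exceeded the homozygote in 65.2% and 55.0% of them. Of the same probe sets 36 and 24 were called in homozygous minus heterozygous. The count of 2042 fell to 1320 without heterozygous replicate 1, 1155 without heterozygous replicate 2 and 618 in the AH85 to AH92 series. Array weights raised it to 3464.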

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

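The tests of scaling, code series, insertion, ripening stage, cross-reaction and sample identity in this part were chosen only after the results were seen.

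Pathogenesis-related transcripts were higher in both ORR genotypes, with list medians of 2.09 and 2.22. The size of the spike shifts argues against a difference in scaling or RNA input as the source of a rise this large. The poly-A spikes shifted by -0.15 and -0.34, the hybridization spikes other than bioC by -0.48 and -0.41, and bioC by -0.57 and -0.53. These shifts (homozygous and heterozygous minus wild type) were all smaller in size than the rise. Their direction was not used as evidence. The code series did mark the arrays, with bioC lower by 1.17 in AH105 to AH108. Each genotype had 1 array in that series, so an offset shared by the series could not give a difference between genotypes. The homozygous median was 2.13 in the AH85 to AH92 arrays alone, so the rise does not rest on AH105 to AH108. There the codes run by genotype (homozygous 85 and 86, heterozygous 87 and 88, wild type 89 and 90). An effect of code order within AH85 to AH92 cannot be told apart from genotype. The excision line, with a median of -0.46, lacked the rise, as a dependence on the insertion would give if that line has lost it. The rule for this test asked only that no such rise be present, so a fall met it as well. Loss alone would give a return to the wild-type level, and the called decreases in that line, given above, go beyond this. The reporter probe sets still read above wild type there, so the loss is taken from the label. What stays open is any growth or infection difference shared by the plants of a genotype, which was not tested.

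RIN and NOR were higher in both ORR genotypes. Fruits further along in ripening may be a candidate explanation. Of the other ripening genes given above, E8, PG2 and ACS2 did not pass in either ORR genotype and ACS4 was lower in both. Psy1 was called higher in homozygous fruits on its brightest probe set. The ripening-induced list, which holds RIN and NOR, did not pass, so no shift of that list as a whole was seen. The light-reaction list, which falls as fruits ripen, had a median of 0.76 in homozygous minus wild type. A difference in stage alone does not account for both changes. Whether the mutation, in a gene of a plastid complex, raises these transcripts itself was not tested, so stage stays open for RIN and NOR. The mean change of RIN and NOR, homozygous minus wild type, was 3.58 in the AH85 to AH92 arrays alone. The rise thus does not rest on the AH105 to AH108 arrays. As above, the codes run by genotype within AH85 to AH92, so an effect of code order there cannot be told apart from genotype. In AH105 to AH108, where the order differs, the ORR arrays also lay above the wild-type and excision arrays for both genes. A probe set that reads another transcript cannot be told apart from a rise in RIN or NOR, because there were 0 further probe sets for them. A difference between the genotypes themselves stays open.

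Excision replicate 3 lay nearer to wild type than the other excision arrays, and the count of 722 against wild type rose to 1831 without it. A wild-type sample under its label is argued against by the reporter probe sets, on which it lay at least 1.50 log2 units above every wild-type array. The annotation does not say what these probe sets read, so this rests on their signal alone. The code series is argued against because excision replicates 2 and 3, of the same series, lay 34.3 apart on the second principal component and replicates 1 and 2 lay 13.4 apart. Wild-type RNA mixed into replicate 3 cannot be told apart from variation among excision fruits, since its fall below the mean of replicates 1 and 2 ran from -0.28 to -1.64 over the reporter probe sets and with a single array no spread is known. No biological explanation was tested.

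Control probe sets outside the comparisons showed a signal that differed from wild type: the 3 sections of the GlutTrans control were higher in homozygous fruits by 1.25 (3′), 0.69 (5′) and 1.06 (middle), with adjusted p of 0.000121, 0.000435 and 0.000331 in limma over 25 tomato controls. In heterozygous fruits they were higher by 1.26, 0.41 and 0.95, with adjusted p of 0.000112, 0.0220 and 0.000861.

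The change against wild type differed between homozygous and heterozygous fruits for 15 genes with a symbol, by the test of the difference itself. The 13 with an informative symbol are given here, and 2 with placeholder symbols are left out by the naming rule. It was lower in homozygous fruits for h52 (-1.76), ctu1 (-1.44), PR-5 (-1.30), LCA1 (-1.01), rnalx (-0.83), CEVI57 (-0.82), MADS1 (-0.72), MYB (-0.56) and SODCP.2 (-0.46). It was higher for NCED1 (0.69), gtsatom (0.80), LOC543809 (1.15) and TAS14 (1.44). Against wild type h52 changed by -0.31 in homozygous and 1.45 in heterozygous fruits, and PR-5 by 0.43 and 1.73. The 2 probe sets of gtsatom differed in sign in homozygous minus wild type. With 1 array left out at a time, 11 of the 13 lost the call at least once, and h52 and PR-5 kept it. Without homozygous replicate 3 all 11 lost it (adjusted p from 0.0581 to 0.191), and without homozygous replicate 2 (0.0601 to 0.175), heterozygous replicate 1 (0.0673 to 0.189) or heterozygous replicate 2 (0.0631 to 0.176) 10 did. Without heterozygous replicate 3 the number was 7 (0.0529 to 0.138), and it was 5 without homozygous replicate 1 (0.0538 to 0.0945) or wild-type replicate 1 (0.0605 to 0.0860). It was 3 without excision replicate 1 (0.0538 to 0.0716) or 2 (0.0513 to 0.0547), and 1 without wild-type replicate 2 (0.0673) or 3 (0.0677).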

How the results depend on the processing

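All alternatives in this part were planned, and the splits of the arrays were planned too. In the AH85 to AH92 arrays alone, with 2 per group, limma called 2027 (homozygous minus wild type), 2442 (heterozygous minus wild type), 0 (excision minus wild type, with 1792 at an unadjusted p under 0.05), 1808 (homozygous minus excision), 12 (homozygous minus heterozygous) and 618 (off the midpoint). A 2-fold minimum, which removes calls by construction, gave 762, 912, 146, 900, 30 and 315 in the same order. Array weights gave 5458 for homozygous minus wild type, 1871 for excision minus wild type, 408 for homozygous minus heterozygous and 3464 off the midpoint, and the cause was not tested. Fitting only the compared groups gave 23 for excision minus wild type, with fewer arrays to estimate the spread. Of 100 tests of lists 17 passed with the preset correlation, 0 with an estimated correlation and 46 with fry, which asks a different question.

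With 1 array left out, counts ran from 2461 to 3697 (homozygous minus wild type), 3167 to 4312 (heterozygous minus wild type), 136 to 1831 (excision minus wild type), 2636 to 3841 (homozygous minus excision), 27 to 91 (homozygous minus heterozygous) and 1155 to 2288 (off the midpoint). The share with the same sign on other arrays ran from 90.2% to 95.7% for homozygous calls and 87.4% to 94.1% for heterozygous calls, and the lists that passed from 15 to 21. The remaining counts stayed within 1.5 times their value. With the replicate number as a block, 1059 were called in excision minus wild type and 82 in homozygous minus heterozygous, but the numbers pair the arrays only in part. After removing genotype means 6 of 12 arrays correlated best with an array of their own number; r was over 0.1 in 6 of 6 pairs for replicate 1, which is the AH105 to AH108 series, 3 of 6 for replicate 2 and 2 of 6 for replicate 3. With the code series as a block these counts were 930 and 114. Of 250 called results of named genes 165 kept the call under every alternative run, 85 lost it under at least 1, and 0 reversed. By comparison those kept were 54 of 68 (homozygous minus wild type), 53 of 65 (heterozygous minus wild type), 0 of 35 (excision minus wild type), 57 of 69 (homozygous minus excision) and 1 of 13 (homozygous minus heterozygous). Of the 287 named results, called or not, 235 were on probe sets bright enough to be run without dim probe sets. Genes named for large changes do not stand for all calls. Median centring and the 2-fold minimum each turned the majority direction of the calls in each of the comparisons except homozygous minus heterozygous. The alternative offset before the log was not run, since the values were already log2.

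Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split, 1 of 10 with as many calls in each comparison, gave 3516 against at most 1 in the others (homozygous minus wild type), 4100 against 0, 722 against 226 (excision minus wild type, with excision replicate 3 joined to wild-type replicates 1 and 2), 3516 against 0 (homozygous minus excision) and 85 against 0. For the midpoint 2 of 100 splits called 2042 or more, the real split itself and 1 other. That other, at 4244, had the wild-type arrays in the heterozygote's place. Splits that mix genotypes put the difference between those genotypes into the spread, so few or no calls follow from their make-up. This holds for every split into 3 and 3 other than the real one. The splits therefore do not test the counts of the comparisons, and mixed splits do not test a departure from the midpoint. Signal over background limits what dim probe sets can show; without them 703 were called in excision minus wild type.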

Other observations

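The test of reporter dose in this part was chosen only after the result was seen, and the rule for judging it was changed more than once after that. Several genes outside the lists changed strongly in both ORR genotypes. GLB2, a non-symbiotic haemoglobin gene, rose from 7.30 ± 0.16 (log2, SD, n = 3) in wild type to 10.53 ± 0.35 in homozygous and 10.78 ± 0.03 in heterozygous fruits, and TLRP rose from 6.23 ± 0.82 to 11.84 ± 0.16 and 10.67 ± 0.17. ODD rose from 6.60 ± 0.59 to 10.01 ± 0.61 and 11.65 ± 0.50. The phospholipase D gene PLDb2 fell by 2.23 (SE 0.26) and 2.70 (SE 0.26), and the WRKY gene LOC543855 by 2.73 (SE 0.40) and 2.97 (SE 0.40), in homozygous and heterozygous fruits.

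A hypothesis was that 2 insertion copies may give more reporter transcript than 1. On RPTR-Les-A06498-1_at, the reporter probe set with the largest change against wild type among the 63, homozygous minus heterozygous was -0.84. All 3 heterozygous arrays (12.14 or higher) lay above all 3 homozygous arrays (11.46 or lower), where chance gives 10% for a separation in either direction. An earlier form of the rule took this as evidence against the hypothesis. It is left open here, because the annotation does not identify what the probe sets read and the excision line still read 3.91 above wild type on this one (SE 0.41, adjusted p = 0.00107), so the copies of the sequence are not known. The difference did not pass in the fit of 4 genotypes (SE 0.41, adjusted p = 0.673), whose spread includes the excision arrays (SD 1.13), and passed with the ORR arrays alone (SE 0.09, adjusted p = 0.0179). RPTR-Les-U57609-2_s_at differed by -0.93, also without overlap (adjusted p = 0.714, and 0.0672 with the ORR arrays alone). RPTR-Les-X17220-1_at differed by -0.64 with overlapping arrays (adjusted p = 0.963, and 0.816 with the ORR arrays alone), and was highest in the excision line (8.91 against 7.06 in homozygous fruits).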
